A study of Mus musculus with 6 samples.

How the data were processed

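The study measured RNA from whole livers of 12-week-old mice on a C57BL/6 background that were fed chow and left untreated. Total RNA was made into libraries with Illumina's TruSeq RNA kit and sequenced on a HiSeq2500, per the labels' protocols. The knockout group lacked AEG-1, the product of the Mtdh gene, in hepatocytes. The control group carried the conditional allele without the deletion, per the series description, and its sample titles call it wild type. The labels describe 3 adult mice per group and number the libraries of each group 1 to 3.

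The authors deposited 1 table of whole-number read counts per gene, not normalized, with 46983 rows and 6 library columns. The submitters' processing notes name FastQC, Trimmomatic 0.33, Subread 1.4.6-p4 and featureCounts 1.4.6-p4 and the genome builds mm10 and GRCm38, which are 2 names of the same assembly. Per the file headers, each row gives an Ensembl mouse gene identifier, the exon coordinates, the strand and the summed exon length in bases. The strand setting of the counting, the treatment of reads with several matches and the annotation release are not given in the sources used here. Counts of genes with near-identical copies, and of overlapping genes on opposite strands, are therefore uncertain. Symbols and gene types came from GENCODE vM21, which holds 46488 of the identifiers and is on the same build. Of those rows, 39685 had the same span in both, and 99.95% of the spans overlapped. All 37 rows of mitochondrial genes held 0 in every library, so mitochondrially encoded transcripts could not be compared.

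The columns of control replicates 1 and 2 were identical in all 46983 rows. They therefore differed by less than the sampling noise and were counted as 1 library, here called control replicate 1. The other pairs of libraries differed by a chi-square per degree of freedom of 44.5 to 227 over genes with at least 10 counts in the pair. The design fixed before the data were examined was 3 libraries against 3. The comparison made was 3 knockout libraries against 2 distinct control libraries, and a fit on all 6 columns as deposited was added as an alternative after the duplicate had been seen. The labels call the libraries biological replicates from separate mice.

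Library totals ran from 29557477 to 33685670 counts. A count of 3 corresponds to 0.101 CPM (counts scaled to a library's total) in the smallest library and 0.089 in the largest. These limits cover counting error only, because the reads carry no molecular identifiers.

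Genes were kept by edgeR's filterByExpr, which left 16441. Scaling factors were computed by the trimmed mean of M values (TMM), and CPM values quoted for single genes were divided by them. The groups were compared with edgeR's quasi-likelihood F test, two-sided, without the robust prior, and p-values were adjusted by the Benjamini-Hochberg method over all kept genes with a threshold of 0.05. Errors of log2 fold changes were derived from the F statistic. Means are given with the SD over the distinct libraries. Software versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, BLAST+ 2.17.0 and Python 3.11.15.

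Before the data were examined, 42 gene lists were written down, covering liver pathways and markers of the cell types that a liver sample can hold. The 35 lists with at least 5 kept members were tested with limma's camera on voom values at a preset correlation between genes of 0.01. The same lists were tested with the correlation estimated from the data and with fry. Adjusted p-values of lists are Benjamini-Hochberg values over the tested lists. Symbols without a match, such as Ahsp, were left out, and the Y-linked genes and Xist were not tested as a list. The genes named in the text followed a rule fixed in advance: Mtdh, up to 8 genes in each direction with the largest changes among those past the threshold with a mean of at least 2 CPM and non-overlapping groups, and the 3 members of every list with the smallest p. Only Mtdh met the threshold part of the rule, and the rule named 115 genes. Genes outside it are stated to have been chosen after their values were seen.

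The gene test was checked on simulated counts drawn from the means, dispersions and library sizes of the real data, 3 libraries against 2, over 16441 genes and 5 simulations. It called 4.8% of genes changed 1.5-fold, 50.8% of those changed 2-fold, 98.4% of those changed 4-fold and 99.6% of those changed 8-fold. It also called 0.1% of unchanged genes, 73 of 79887, beside 12, 127, 246 and 249 changed genes at these folds. False calls thus made up a larger share of all calls than the adjusted threshold allows for. The changed genes were drawn from those with a mean of at least 5 CPM, with 250 per fold over the 5 simulations. That many changed genes make the adjusted threshold easier to reach, so these shares can overstate recovery where few genes change. The list test was checked in the same simulations, in which genes were independent of each other. It called a lipogenesis list raised by 0.5 on the log2 scale in 5 of 5 simulations, and 1 other list in total. The real lists had estimated correlations of up to 0.779, for sinusoidal endothelial markers. A check on independent genes therefore cannot bear on the calls made at the preset correlation.

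The alternatives were RLE, upper-quartile and library-total scaling, TMM without genes that took at least 1% of a library, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2, limma-voom with and without quality weights, the robust prior, an added fold threshold, removal of a gene-length trend per library, the replicate number as a block (with the identical control column as number 1 and, added after the duplicate had been seen, as number 2), and leaving out each replicate in turn, which was added for DESeq2 after its calls had been seen. Leaving out control replicate 1 removed both identical columns. For the tests of the closing section, kept pseudogenes were matched to their closest protein-coding transcript with BLAST+.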

Results

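Livers of mice with a hepatocyte-specific deletion of AEG-1 were compared with livers of control mice to ask which transcripts differ when hepatocytes lack this protein. AEG-1 (astrocyte elevated gene 1) is encoded by Mtdh and is known as a membrane and RNA-binding protein with roles in cancer and inflammation. Expression is given as CPM, counts scaled to the size of the library. The count table held 6 library columns, 3 per group. The columns of control replicates 1 and 2 were identical in every row, so they differed by less than the sampling noise and were counted as 1 sample, which left 3 knockout and 2 distinct control libraries. Library totals were 29557477, 32335414 and 33685670 counts in the knockout group and 30819997 and 30965664 in the control group. All libraries had counts of the Y-linked genes, with 2519 to 3247 counts of Ddx3y, and 1 to 6 counts of Xist.

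Mtdh transcripts were almost lost from the knockout livers. Mtdh (ENSMUSG00000022255, chromosome 15, 34082694 to 34142386 on GRCm38) had 2.50 ± 0.350 CPM in the knockout livers (SD, n = 3) and 51.3 ± 4.67 CPM in the control livers (SD, n = 2). The knockout libraries held 89, 74 and 76 Mtdh counts, against 1529 and 1612 in the control libraries, so every library went with its label. The knockout level was 4.9% of the control level, a 20.5-fold difference, with a log2 fold change of -4.36 (SE 0.15). This passed the edgeR quasi-likelihood test with an adjusted p of 0.000564.

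**Figure D1:**
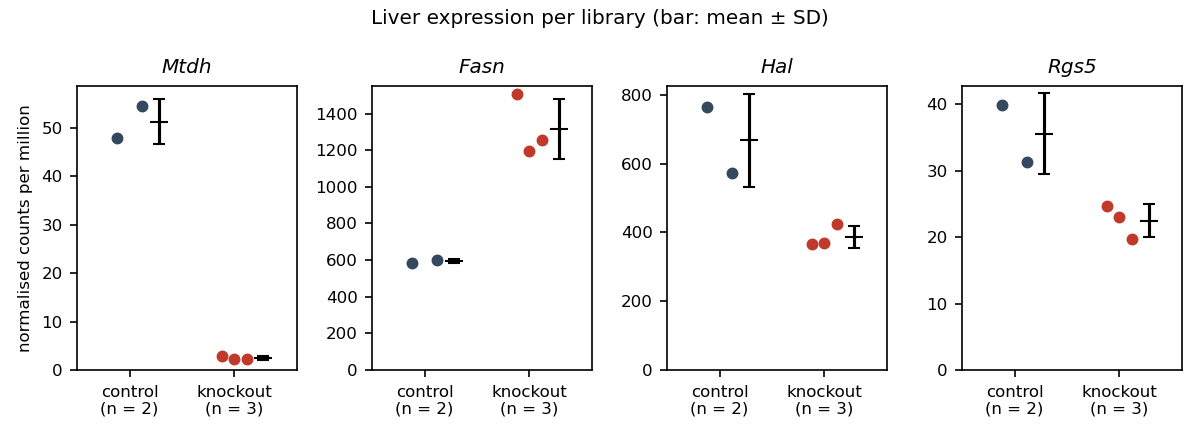
Normalised CPM (vertical axes, starting at 0) of Mtdh, Fasn, Hal and Rgs5 in each distinct library, with points for libraries and bars for the mean ± SD (control n = 2, knockout n = 3). In each panel the libraries of the groups do not overlap, and Mtdh lies at 2.50 CPM in the knockout group against 51.3 CPM in the control group.

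No other gene passed the threshold by edgeR. Of 16441 genes tested, 0 were higher and 1, Mtdh, was lower in knockout livers by the edgeR quasi-likelihood test. At an unadjusted p under 0.05 there were 268 higher and 296 lower genes, 564 in all, where chance alone gives 822. DESeq2 called 7 genes higher and 11 lower, and limma-voom called 0 higher and 1 lower. The DESeq2 calls, 18 in all, numbered 6, 48 and 68 without knockout replicates 1, 2 and 3, and 26 and 144 without control replicates 1 and 3. One of the 7 higher genes was Ckm, a creatine kinase of skeletal muscle named here after its values were seen, with 153 counts in knockout replicate 1 and 0 in every other distinct library. The 95% interval of the log2 fold change lay within 1 of 0 for 12295 genes, and its median half-width was 0.46. The groups did not overlap in 16.9% of the genes, where chance gives 20%. The control libraries differed from each other more than any other pair of libraries, with a chi-square per degree of freedom of 227. The count of lower genes was 6 without control replicate 3, which left a single control library.

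**Figure D2:**
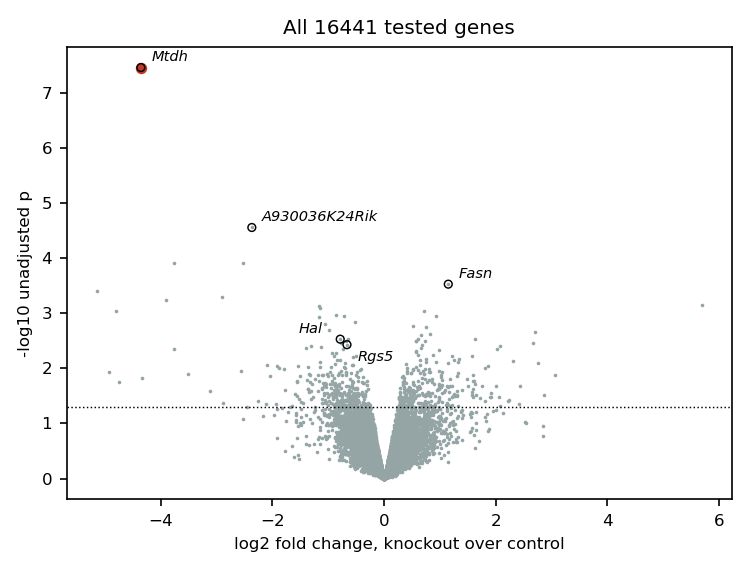
Log2 fold change of knockout over control (horizontal axis) against -log10 of the unadjusted edgeR p (vertical axis) for the 16441 tested genes, with 5 genes labelled, A930036K24Rik being the gene with the second lowest p and chosen after its values were seen. Mtdh, the filled point, is the 1 gene past the adjusted threshold, and the dotted line marks an unadjusted p of 0.05.

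Among the 35 gene lists tested, lipogenesis and triglyceride synthesis had the highest median log2 fold change. Of its 27 genes, 26 were higher in knockout livers, with a median of 0.47, and the knockout libraries lay above the control libraries in the mean of the list. The groups did not overlap in the mean of 3 of the 35 lists (8.6%), where chance gives 20%. The summed adipocyte markers were at 24.9, 32.6 and 10.9 CPM in the knockout libraries and 12.7 and 13.3 CPM in the control libraries. Of these markers, Plin4 had a log2 fold change of 1.21 (SE 0.49), Cidea 1.13 (SE 0.49) and Cfd 1.58 (SE 0.71), none past the edgeR threshold, while DESeq2 called Plin4 without knockout replicate 3. The others of that list, named after their values were seen, were Fabp4 with -0.06 (SE 0.26), and Adipoq, Lep and Plin1 with at most 1 count each in any library. The lipogenesis list rose in the camera test with an adjusted p of 6.52e-13, but with adjusted p = 0.437 with an estimated correlation. Fasn, the fatty acid synthase, had 1318 ± 164 CPM in knockout and 593 ± 10.2 CPM in control livers, a log2 fold change of 1.15 (SE 0.17). Its edgeR adjusted p was 0.970 over all genes and 0.00797 adjusted over the list alone, where it was the 1 gene of the list to pass. DESeq2, by contrast, called Fasn over all genes with an adjusted p of 4.03e-09, and still called it without each knockout library in turn. Acacb, an acetyl-CoA carboxylase, had a log2 fold change of 0.98 (SE 0.23), and Elovl6, a fatty acid elongase, one of 1.04 (SE 0.32), neither past the edgeR threshold, while DESeq2 called Acacb without knockout replicate 3 and Elovl6 without knockout replicate 2.

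Targets of PPAR-alpha, the nuclear receptor that drives fatty acid oxidation, were higher for 47 of 48 genes, with a median of 0.26 and a camera adjusted p of 3.11e-10 (adjusted p = 0.605 with an estimated correlation). The libraries overlapped, with the list's mean in knockout replicate 3 close to the controls. The summed adipocyte markers were likewise higher in knockout replicates 1 and 2 (24.9 and 32.6 CPM) than in knockout replicate 3 (10.9 CPM) and the controls (12.7 and 13.3 CPM). Within the PPAR-alpha list, the acyl-CoA thioesterase Acot3 had 31.4, 3.86 and 8.97 CPM in the knockout libraries against 2.01 and 1.49 CPM in the control libraries. Acot4 had a log2 fold change of 1.15 (SE 0.39) and the monoacylglycerol lipase Mgll one of 0.61 (SE 0.21), and no member passed over all genes by edgeR, while DESeq2 called Acot3 and Acot4 without knockout replicate 2 and Mgll without control replicate 3. Genes of cholesterol synthesis and SREBP2 targets were higher for 22 of 28 (median 0.14, camera adjusted p 0.0173, and adjusted p = 0.729 with an estimated correlation). On the voom scale, here and below for medians without a library, that median was -0.15 without control replicate 3 and 0.03 without knockout replicate 2, where the call was lost, and 0.36 without control replicate 1 and 0.28 without knockout replicate 3. The call was also lost on all 6 columns as deposited (0.05). Tmem97 had the smallest p of that list, with a log2 fold change of 0.34 (SE 0.11).

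In the glucose metabolism list, 19 of 23 genes were higher (median 0.26, camera adjusted p 4.77e-05, and adjusted p = 0.565 with an estimated correlation). The glycolytic enzyme Eno1 had 94.2 ± 6.26 CPM in knockout and 61.7 ± 7.53 CPM in control livers, and Pfkfb1 had a log2 fold change of 0.34 (SE 0.11). The nuclear-encoded respiratory chain list had 69 of 77 genes higher, each by little (median 0.07, camera adjusted p 9.49e-05, and adjusted p = 0.711 with an estimated correlation). Genes of xenobiotic metabolism were higher for 22 of 31 (median 0.15, camera adjusted p 0.0192, and adjusted p = 0.628 with an estimated correlation). Alas1, the first enzyme of haem synthesis, varied from 235 to 1218 CPM among the knockout libraries, and DESeq2 called it without knockout replicate 2. It lies on chromosome 9 between 105 and 110 Mb, like A930036K24Rik, a gene chosen after its values were seen, where 7 of 105 tested genes had an unadjusted p under 0.01. These 3 lists overlapped between the groups in their mean per library. The glucose median was 0.17 without control replicate 1, and the respiratory chain median was 0.01 without knockout replicate 3, where the call was lost, and 0.12 without knockout replicate 2. The xenobiotic call was lost without control replicate 1 (median 0.04), knockout replicate 1 (0.06) and knockout replicate 3 (0.05), and the median was 0.29 without knockout replicate 2 and 0.30 without control replicate 3. Slc10a1, the bile acid uptake transporter, had a log2 fold change of 0.37 (SE 0.14) in the bile acid list, which did not pass the camera test.

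The medians of the 2 hepatocyte zone lists had opposite signs, and the difference between the zones was not tested. All 10 pericentral markers were higher (median 0.17, camera adjusted p 0.00926, and adjusted p = 0.565 with an estimated correlation), with 0.47 (SE 0.18) for Glul, the glutamine synthetase of the cells around the central vein. Of 10 periportal markers, 8 were lower (median -0.40, camera adjusted p 0.00167, and adjusted p = 0.605 with an estimated correlation). Hal, the histidine ammonia-lyase, had 388 ± 32.0 CPM in knockout and 668 ± 135 CPM in control livers, a log2 fold change of -0.79 (SE 0.17). Hal was the 1 periportal marker to pass when adjusted over the list alone, with 0.0294, and its edgeR adjusted p over all genes was 1. DESeq2 called Hal over all genes with an adjusted p of 0.0237, a call lost without knockout replicate 1 or 2 or control replicate 1. The amino acid and urea cycle list, as fixed in advance, shares Hal, Sds, Gls2, Ass1 and Arg1 with the periportal markers. It also shares Glul and Oat with the pericentral markers, so its call is not independent of theirs. In this list, 22 of 30 genes were lower (median -0.12, camera adjusted p 0.00544, and adjusted p = 0.605 with an estimated correlation). Hal did not pass when its edgeR p was adjusted over that list alone (0.0883). The 10 general hepatocyte markers did not pass (median -0.04, camera adjusted p 0.933). Each of these called lists overlapped between the groups in its mean per library. All 3 calls were lost without knockout replicate 2 and without control replicate 1, where the medians were 0.18 and 0.16 for pericentral, -0.16 and -0.15 for periportal and -0.05 and -0.03 for amino acid genes. The periportal median was -0.73 and the amino acid median -0.22 without control replicate 3, the pericentral median was 0.37 without knockout replicate 3, and the amino acid median was -0.20 without knockout replicate 1 or 3.

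Inflammatory and matrix genes were lower. Of 22 NF-kB inflammatory genes, 16 were lower (median -0.15, camera adjusted p 0.0233, and adjusted p = 0.565 with an estimated correlation). The chemokine Cxcl1 had 8.44 ± 3.22 CPM in knockout and 22.3 ± 7.60 CPM in control livers, a log2 fold change of -1.40 (SE 0.33). It was short of the edgeR threshold, while DESeq2 called it without knockout replicate 3 and without control replicate 1. Of 25 acute phase proteins, 21 were lower (median -0.16, camera adjusted p 0.00926, and adjusted p = 0.605 with an estimated correlation), with -0.50 (SE 0.13) for Steap4. Of 26 fibrosis and matrix genes, 22 were lower (median -0.33, camera adjusted p 2.92e-06, and adjusted p = 0.605 with an estimated correlation). Among them, Acta2, the smooth muscle actin of activated stellate cells, had a log2 fold change of -0.94 (SE 0.23) and the collagen gene Col1a1 one of -0.70 (SE 0.19). The unfolded protein and integrated stress response list had 19 of 26 genes lower (median -0.15, camera adjusted p 0.0434, and adjusted p = 0.605 with an estimated correlation), while its member Asns ranged from 2.13 to 13.2 CPM between the control libraries. The knockout libraries lay below the control libraries in the mean of the NF-kB list and of the matrix list, and overlapped in the other lists named here. The NF-kB call was lost without knockout replicate 2 (median -0.13), knockout replicate 3 (-0.10) and control replicate 3 (-0.09), without a low-count filter (-0.16) and on all 6 columns as deposited (-0.14). The acute phase call was lost without knockout replicate 1 (-0.08), knockout replicate 3 (-0.05) and control replicate 3 (-0.39), and the median was -0.47 without knockout replicate 2. The stress response call was lost without knockout replicate 1 (-0.12), knockout replicate 3 (-0.11) and control replicate 1 (-0.08), and the median was -0.27 without knockout replicate 2. It was also lost with upper-quartile or library-total scaling and on all 6 columns as deposited. The matrix median was -0.15 without knockout replicate 3.

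Markers of non-hepatocyte cells were lower beside these inflammatory and matrix genes. Of 12 sinusoidal endothelial markers, 11 were lower (median -0.34, camera adjusted p 1.40e-06, and adjusted p = 0.605 with an estimated correlation), with -0.69 (SE 0.23) for Pecam1 and -0.57 (SE 0.19) for Cdh5. Of 13 Kupffer cell and macrophage markers, 12 were lower (median -0.17, camera adjusted p 0.00461, and adjusted p = 0.605 with an estimated correlation). Of 10 stellate cell markers, 9 were lower (median -0.15, camera adjusted p 0.0263, and adjusted p = 0.631 with an estimated correlation). Rgs5, a pericyte gene, had 22.5 ± 2.49 CPM in knockout and 35.6 ± 6.09 CPM in control livers, and passed when adjusted over the list alone with 0.0371. All 5 erythroid markers were lower (median -0.27, camera adjusted p 0.0246, and adjusted p = 0.605 with an estimated correlation). These 4 lists overlapped between the groups in their mean per library. The endothelial call was lost without control replicate 3 (median -0.23), and the median was -0.21 without knockout replicate 3, -0.54 without knockout replicate 1 and -0.56 without control replicate 1. The macrophage call was lost without control replicate 3 (0.02) and knockout replicate 2 (-0.11) and on all 6 columns as deposited (-0.10), and the median was -0.35 without control replicate 1. The stellate call was lost without knockout replicate 3 (-0.03), control replicate 1 (-0.16) and control replicate 3 (-0.17), with quality weights (-0.10) and on all 6 columns as deposited (-0.16). The erythroid call was lost without control replicate 1 (0.10), knockout replicate 1 (-0.28) and knockout replicate 3 (-0.14), and the median was -0.41 without knockout replicate 2 and -0.55 without control replicate 3. Cholangiocyte markers (6 of 8 lower, camera adjusted p 0.118), T and NK cell markers (5 of 6 lower, 0.0794) and B and plasma cell markers (6 of 9 lower, 0.719) did not pass. Cholangiocyte markers passed without control replicate 1 (-0.40), T and NK cell markers without a low-count filter (-0.63), and B and plasma cell markers in opposite directions without control replicate 1 (0.47) and control replicate 3 (-0.55).

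The remaining lists did not pass the camera test. Their adjusted p-values were 0.0585 for lipoprotein assembly and clearance, 0.120 for bile acid synthesis and transport, for interferon-stimulated genes and for cytosolic ribosomal proteins, 0.139 for female-biased and 0.266 for male-biased liver genes, and 0.422 for LXR targets. They were 0.408 for the circadian clock, 0.444 for retinoid metabolism, 0.451 for fetal liver and tumour markers, 0.589 for heat shock chaperones, 0.771 for the cell cycle, 0.819 for the growth hormone and IGF axis and 0.969 for NRF2 targets. The median and the direction of the test differed in sign for NRF2 targets, the circadian clock, the cell cycle and the hepatocyte markers. Some of these lists passed in other fits. Ribosomal proteins passed without control replicate 1 (median 0.21), knockout replicate 1 (0.09) and knockout replicate 2 (0.09), and in the opposite direction without control replicate 3 (-0.13). Interferon-stimulated genes passed without knockout replicate 3 (0.23) and control replicate 3 (0.18), and bile acid genes without knockout replicate 2 (0.11). Male-biased genes passed without knockout replicate 3 (-0.47) and control replicate 1 (-0.42) and with quality weights (-0.33). Female-biased genes passed without knockout replicate 3 (0.40), without a low-count filter (0.33) and with quality weights (0.35), and lipoprotein genes without control replicate 1 (0.14), without a low-count filter (0.12) and with quality weights (0.13). Cd24a of the tumour marker list had 1.16 CPM in knockout and 2.16 CPM in control livers, and Hmox1 of the NRF2 list had a log2 fold change of -0.48 (SE 0.17), both short of the edgeR threshold.

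**Figure D3:**
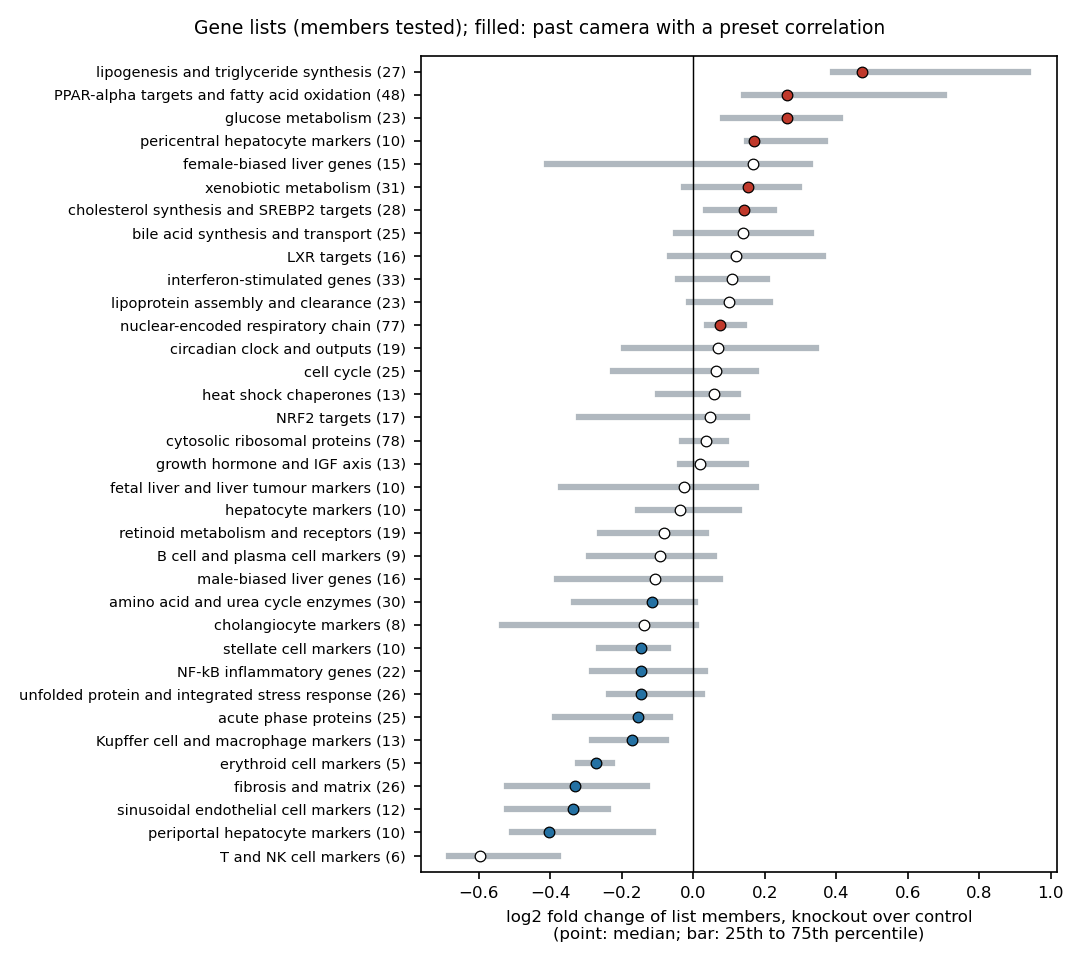
Median log2 fold change, knockout over control, of the tested members of each of the 35 gene lists (points), with bars from the 25th to the 75th percentile of the members and the number of members in brackets. Filled points mark the 17 lists past camera with a preset correlation, 7 higher and 10 lower, from 0.47 for lipogenesis to -0.40 for periportal markers, and none of them passed with an estimated correlation.

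In all, 17 of 35 lists passed camera with the preset correlation, 7 higher and 10 lower, and 0 passed with an estimated correlation, where 1 list had an unadjusted p under 0.05, or by fry, where 2 did. Lipogenesis, PPAR-alpha targets, glucose metabolism and the matrix list passed in each of the 5 fits that left out 1 library, and the other 13 were lost in at least 1 of them. No gene of any list passed over all genes by edgeR, and only Fasn, Hal and Rgs5 passed over a list alone. Each list was adjusted by itself, without a correction over the 35 lists, so some such passes can arise by chance. Hal passed over the periportal list but not over the amino acid and urea cycle list. Too few members were kept to test neutrophil and monocyte, adipocyte, mesothelial, pancreatic acinar and skeletal muscle markers. The summed skeletal muscle markers reached 26.7 CPM in knockout replicate 1 and at most 0.178 CPM in the other libraries, and that library also held all counts of Ckm.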

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

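Settings were fixed before the data were examined, except a second replicate block given below, the fit on all 6 columns as deposited, added after the duplicate was seen (0 genes higher, 1 lower, 12 lists), and DESeq2 without each library in turn, added after its calls were seen. The latter gave 2, 35, 43, 15 and 91 genes higher, 4, 13, 25, 11 and 53 lower and 2, 8, 7, 4 and 13 named genes, Mtdh and Fasn each time, without knockout replicates 1, 2 and 3 and control replicates 1 and 3. Mtdh kept its direction in all 24 alternatives that gave it a value, with log2 fold changes from -4.48 to -4.26 and adjusted p-values from 6.29e-98 (DESeq2) to 0.0517, and passed in all but the replicate block. In that block, which gives the identical control column number 1, -4.28 no longer passed, 0 genes were lower and 0 named genes passed, with 1 residual degree of freedom. It gave 15 lists: 5 of the 17 calls were lost (cholesterol synthesis, amino acid and urea cycle, pericentral, periportal and macrophage), 3 were gained (LXR targets, retinoid metabolism and ribosomal proteins), and 6 medians of lists that had not passed changed sign. The replicate numbers share only a number: deviations from the group means correlated by 0.076 for number 1 and 0.158 for number 3, the 2 control values mirroring each other, and knockout replicate 2 stood unpaired in the block. Whether the identical column belongs to control mouse 1 or 2 is unknown. A block that gives it number 2, added after the duplicate was seen, kept Mtdh past the threshold (-4.47) with 0 genes higher, 1 lower and 18 lists, lost xenobiotic metabolism and gained ribosomal proteins and T and NK cell markers, and knockout replicate 2 correlated with it by 0.101. DESeq2 called 7 genes higher, 11 lower and 3 named genes (Mtdh, Fasn with adjusted p 4.03e-09 and Hal with 0.0237), and no low-count filter gave 3 lower genes (Mtdh, A930036K24Rik and Gm3191, the last 2 chosen after their values were seen); the cause was not tested. Outside the DESeq2 fits, no named gene but Mtdh passed in any alternative.

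Fits with edgeR that left out 1 library gave 0 higher genes and 1 to 6 lower genes, -4.47 to -4.26 for Mtdh, 1 named gene and 13 to 16 lists. Where a single control remained, it is assumed to vary like the knockouts. The 6 genes without control replicate 3 were Mtdh and 5 small RNA genes of the control left over, such as Gm25679, chosen likewise, with 11.5 CPM there and at most 0.326 CPM in every other library. The 17 list calls fell to 0 with an estimated correlation (lowest adjusted p 0.437) and to 0 by fry (0.443), and other settings gave 12 to 21. Of the 17, 4 were lost without knockout replicate 1, 6 without knockout replicate 2, 7 without knockout replicate 3, 7 without control replicate 1 and 6 without control replicate 3. Over these fits, medians ran from -0.55 without control replicate 3 to 0.47 without control replicate 1 for B and plasma cell markers (adjusted p 0.0194 in the latter), from -0.15 (0.0991) to 0.36 for cholesterol synthesis and from -0.13 (0.0055) to 0.21 for cytosolic ribosomal proteins, the low ends without control replicate 3 and the high ends without control replicate 1; fewer libraries entered these fits, and the cause was not tested further. The robust prior and plain limma-voom gave no other list value, because camera already ran on voom. At these depths and group sizes, simulated 2-fold changes were called in 50.8% of genes with a mean of at least 5 CPM. Many changed genes were simulated together, which makes the adjusted threshold easier to reach than in the real data, where 1 gene passed. The share therefore does not give the recovery in this comparison.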

Other observations

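The tests in this part were chosen after the results were seen, except the counts over other splits of the libraries. The genes named here were likewise chosen after their values were seen, apart from Serpina1e, Rpl29, Igfbp1, Ppargc1a, Fasn, Plin4, Cidea and Cfd. DESeq2 called 18 genes (6, 48 and 68 without knockout replicates 1, 2 and 3, and 144 without control replicate 3), among them several that belong to none of the pathway lists. Slc3a1, a subunit of an amino acid transporter, had a log2 fold change of -1.16 (SE 0.21), Dpt, an extracellular matrix protein, one of -1.14 (SE 0.20), and Btg2, an antiproliferative gene, one of -0.86 (SE 0.16). Igtp, an interferon-inducible GTPase, had 0.72 (SE 0.13), Fam84b 0.94 (SE 0.17) and Nat8f7 2.67 (SE 0.60). None of these passed edgeR's adjusted threshold. In each the knockout libraries did not overlap the control libraries, as in 16.9% of all tested genes. Genes picked for a low p on the same libraries mostly show this, so it adds no support.

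Several transcripts set single libraries apart. The major urinary protein genes took 3.83% of the counts in control replicate 1 and 16.3% in control replicate 3, with 6.27%, 7.39% and 12.1% in the knockout libraries. Serpina1e, a male-biased liver gene, had 4348 CPM in control replicate 1 and 363 to 1298 CPM elsewhere. Rpl29, a ribosomal protein gene on chromosome 9, had 0.169 CPM in control replicate 3, 3.64 CPM in control replicate 1 and at least 5.73 CPM in each knockout library. The difference between clock genes of opposite phase was -1.94 on the log2 scale in knockout replicate 2 and -4.47 to -3.80 in the other 4 libraries.

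Low p-values were clustered on chromosome 9: between 105 and 110 Mb, 7 of 105 tested genes had an unadjusted p under 0.01, where 0.568 would be expected, namely A930036K24Rik (-2.37), Col6a5 (-2.90), Ifrd2 (0.52), Rad54l2 (0.75), Gm17040 (2.75), Nudt16 (-0.58) and 4930524O07Rik (1.80). Each had non-overlapping groups, which picking genes by a low p largely brings about. Random placement is argued against, since a share of 2e-04 of 10000 shuffles gave a window as crowded, although shuffling ignores that neighbouring genes can vary together. Tma7 (chromosome 9, 109074568 to 109082587) lies in this window but is not among these 7 genes. The summed CPM of Tma7 and 7 matching pseudogenes changed by 0.00 on the log2 scale, while the pseudogene Gm15610 alone had -2.53. Single rows moved both ways within that sum. The Tma7 row had 15.1, 14.6 and 15.8 CPM in the knockout libraries against 12.6 and 12.8 CPM in the controls, and Gm14200 was also higher. The flat sum argues against a true difference in Tma7 expression behind the shift of Gm15610, and cannot bear on the 7 genes. A strain variant against the reference, carried by one group in this segment, may redirect reads between copies. Of 15 pseudogenes with a p under 0.01, 9 had their closest protein-coding relative (Tma7, Rpl29 or Ctsh) on chromosome 9 between 85 and 115 Mb, against 47 of 2101 others (one-sided Fisher exact p 1.46e-11). With each relative counted once, by its pseudogene with the smallest p, the Fisher exact p was 0.000163. That count favours relatives with many pseudogenes. Rpl29 also differed between the controls, with 3.64 CPM in control replicate 1 and 0.169 CPM in control replicate 3, against at least 5.73 CPM in each knockout library. A variant carried by one whole group does not account for that difference between the controls. The strain variant stays a hypothesis, since the segment was chosen on the same data and no sequence was examined. Of the 18 genes called by DESeq2, a count that single libraries move, 7 lie in that segment or are pseudogenes with a relative there.

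The lipogenesis list was higher in knockout livers by camera at the preset correlation (adjusted p = 0.437 with an estimated correlation), and the mean of its genes was higher in each knockout library than in either control library, a separation seen in 3 of 35 lists (8.6%), where chance gives 20%. The tables argue against adipocytes in the samples, although Plin4 (1.21), Cidea (1.13) and Cfd (1.58) were higher, since Adipoq, Lep and Plin1 summed to at most 1 count in a knockout library while Fasn had at least 39662 there and at most 18671 in a control library. A more fed state of the knockout mice at collection would lower fasting-induced genes. Of 10 such genes, 8 were higher and 2 lower, with a median of 0.19 (bootstrap interval -0.11 to 0.53, 10000 resamples). This argues against a fall of the set larger than the lower end of that interval. A smaller shift cannot be told apart from the genotype, because the interval spans both signs. Single genes with non-overlapping groups went both ways, Igfbp1 lower (-0.75, SE 0.27) and Ppargc1a higher (0.51, SE 0.18). Time of day at collection cannot be told apart from the genotype, because the clock index differed by 0.26 between the groups with overlapping libraries, and 2 controls are too few. That difference rests on knockout replicate 2 (-1.94), since knockout replicates 1 and 3 (-4.27 and -4.47) lay below both controls (-3.80 and -3.84). The loss of AEG-1 itself remains open and untested beyond this comparison. Another split of the libraries set knockout replicate 3 with both controls against the remaining knockouts. It gave a list median of -0.52 on the voom scale, with an unadjusted camera p of 4.26e-13 at the preset correlation. The real split gave 0.45 with 1.86e-14, so a grouping across the genotypes gave a shift about as large. That other split also sets apart the libraries with the higher adipocyte marker sums (24.9 and 32.6 CPM, against 10.9 to 13.3).

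Endothelial, matrix and macrophage lists were lower in knockout livers by camera at the preset correlation, each with adjusted p = 0.605 with an estimated correlation, with no member past the edgeR threshold over all genes, and with groups that overlapped in the mean of the endothelial and macrophage lists. A lower share of all non-hepatocyte cells in the sampled tissue may account for this: the medians were -0.34 for endothelial, -0.17 for macrophage, -0.15 for stellate and -0.14 for cholangiocyte markers, and a permutation test over 43 markers found no difference between these lists (p = 0.627, 100000 permutations). Other non-hepatocyte lists were not in that test, and their medians spread more widely: -0.60 for T and NK cell, -0.27 for erythroid and -0.09 for B and plasma cell markers. A permutation p that misses the threshold does not show equal shifts, and medians moved when single libraries were left out: -0.23 (endothelial), 0.02 (macrophage) and 0.06 (cholangiocyte) without control replicate 3, -0.21 (endothelial), -0.15 (matrix), -0.03 (stellate) and -0.39 (cholangiocyte) without knockout replicate 3, -0.54 (endothelial) without knockout replicate 1, -0.11 (macrophage) and -0.03 (cholangiocyte) without knockout replicate 2, and -0.56 (endothelial), -0.35 (macrophage) and -0.40 (cholangiocyte) without control replicate 1. Medians above 0, as without control replicate 3, go against a lower share of all these cells. A change within these cells that follows from the hepatocyte deletion was not tested and stays open.

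The 5 distinct libraries can be split into 3 and 2 in 10 ways, too few for a share under 0.05. For genes past the threshold, the real split gave 1 and the highest other 5, and 3 of the 10 splits, the real one included, gave at least as many. The split with 5 genes set knockout replicates 1 and 3 with control replicate 3 against the rest, and what sets these libraries apart was not tested. For lists past the camera threshold, the real split gave 17 and the highest other 16, and 1 of the 10 splits, the real one, gave as many.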
